A study of Homo sapiens with 80 samples.

How the data were processed

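CUT&RUN, in which an antibody directs a nuclease to release the chromatin it binds, was carried out in the human liver cancer cell lines HepG2 and HLF with an intact ARID1B gene (WT) or after ARID1B knockout (KO) with CRISPR/Cas9. Cells received 5 µM sorafenib for 48 h or the DMSO vehicle at 0.1%, per the labels. ARID1B, H3K27ac, H3K4me3 and the IgG control were profiled in both lines, FOXA1 and FOXA2 in HLF. The 80 libraries form 40 groups of 2, numbered by the labels as biological replicates 1 and 2. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. HepG2 and HLF libraries were read on different sequencer models, per the labels, so the cell line and the sequencer cannot be told apart.

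Each library had 1 peak list, so replicates were not pooled by the authors. The submitters' processing notes name Bowtie2, MACS2, DESeq2, deepTools and the GRCh38 (hg38) build, with no versions, roles or order. How duplicates, excluded regions, spike-in DNA and the IgG libraries were used is not given in the sources used here. The deposited lists give for each peak its fold enrichment, the −log10 p-value and the −log10 q-value as the authors' peak caller wrote them. The lowest −log10 q in the lists was 1.30, which is a q of 0.05. These peak values are the authors' own. They were used only to filter or rank peaks within 1 list and never compared between lists. The read depth per library is not given in the sources used here. A peak not called may therefore lie under the threshold of a shallower library, and a difference in presence is a difference in calls, not in measured signal.

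Peaks on chromosomes 1 to 22 and X were kept, and overlapping intervals of 1 library were merged into peak regions. Peak region numbers were compared as the mean log2 ratio over strata of 2 against 2 libraries. KO against WT was stratified by cell line and treatment, and sorafenib against DMSO by cell line and genotype. Labels were permuted within strata in two-sided exact permutation tests. With 4 strata the smallest possible exact p is 0.0015. With 2 strata (the FOXA libraries, and ARID1B under sorafenib, tested in WT) it is 0.0556, and within a single group pair an exact test of 2 against 2 gives 0.333 at best. Benjamini-Hochberg adjustment covered the 14 tests of peak numbers. For each antibody and line, the peak regions of the 8 libraries were merged into union regions, present in a library where a peak region overlapped by 1 bp or more. Regions present in 4 of 4 libraries of 1 arm and 0 of 4 of the other are called gained or lost, and their number was set beside that in all 35 splits of the 8 libraries.

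The gene table used (GRCh38.p14, 19974 protein-coding genes) gives both ends of each gene without strand, so transcription start sites, which the design had named, were replaced by gene ends. For each gene the end with a peak within 1 kb in more of the 16 H3K4me3 libraries was used: the lower coordinate for 5932 genes and the higher for 5704. Both ends were kept for 522 genes with equal numbers and for 7816 with no H3K4me3 peak. Distal means over 1 kb from either end of any protein-coding gene. Each gene end was tested with a two-sided exact conditional test on the number of marked libraries, summed over the 4 strata, with Benjamini-Hochberg adjustment over genes able to vary. For 21 gene lists holding 368 genes, the log odds of a mark in the list minus that in all protein-coding genes (0.5 added) was computed per library and tested by the exact stratified permutation test, adjusted over the lists. ARID1B, FOXA1 and FOXA2 binding at H3K27ac regions lost in KO (binding in WT), and FOXA1 and FOXA2 binding at gained ones (binding in KO), was compared with that at kept regions by Mantel-Haenszel odds ratios in 10 bins of peak strength, with 100000 permutations within bins, two-sided, whose smallest p is 1e-05. ARID1B at gained regions is not reported, because choosing regions without H3K27ac in WT itself lowers ARID1B binding in WT. Confidence intervals of these odds ratios are 95% intervals. Co-occupancy was set beside the same regions moved along the chromosome by 100 to 1000 kb in 20 random shifts.

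The design, the alternatives, the lists and the rule for named items were fixed before the data were examined. The rule names, for H3K27ac and per line and contrast, list genes marked in 4 of 4 libraries of 1 arm and 0 of 4 of the other. It adds the 10 genes per direction with the strongest such gene ends (filled up with 4 against 1 or 3 against 0), the 10 smallest p over both lines, and the list members with the largest difference in marked libraries. It also takes the 3 strongest distal regions per direction, the 5 strongest FOXA1 and FOXA2 regions per direction, ARID1B itself, and for H3K4me3 the list genes and the 10 smallest p. The text names a part of these. Alternatives were a −log10 q of at least 5, removal of peaks at IgG peaks, equal peak numbers per library, 1 kb bins, 50% overlap, covered base pairs, a 2 kb window, an unstratified Fisher exact test, other reference genes, no strength bins, sorafenib in place of DMSO libraries, removal of libraries under 1000 regions, a replicate block, and leaving out each library or replicate. Chosen after seeing the data were the use of either gene end, the removal of 4 doubtful libraries, and the comparison of the lines. The doubtful libraries were HepG2 KO sorafenib ARID1B replicate 1, HLF KO sorafenib ARID1B replicate 1, HLF KO sorafenib H3K27ac replicate 2 and HepG2 KO DMSO H3K27ac replicate 2. Motif searches were not run because no genome sequence was used here.

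The tests were also run on simulated data. In simulations of the KO against WT contrast on 19974 genes with 200 gene ends set to a complete change, the exact test at an unadjusted p under 0.05 recovered 100% for both marks. For changes from 0.2 to 0.8 of libraries it recovered 49.0% for H3K27ac and 55.5% for H3K4me3. After adjustment over the 1944 simulated gene ends able to vary, it recovered 100% of complete H3K4me3 changes. It recovered 46.5% of changes from 0.05 to 0.95 and 0% of those from 0.2 to 0.8. For H3K27ac, adjusted over 7069 to 7114 gene ends, it recovered 0% of each. A count of 0 adjusted gene ends therefore says little for H3K27ac. For H3K4me3 it speaks against 200 complete changes but not against changes from 0.2 to 0.8, and fewer than 200 changes were not simulated. For the lists, 2 was added to the log odds of each gene of 1 list, hepatocyte function, in KO libraries. This changed list was called in 86.0% of simulations for H3K27ac and 56.0% for H3K4me3, and other lists in 1.3% and 0.5%. Smaller list changes were not simulated, so a count of 0 passing lists says little about them. The KO test of peak numbers, at an unadjusted exact permutation p under 0.05, called a log2 change of 0.25 in 60.5%, one of 0.5 in 99.5% and no change in 5% of simulations with the replicate SD of H3K27ac (0.19 log2). With that of H3K4me3 (0.12) these shares were 98.5%, 100% and 3.5%. With that of ARID1B (3.17, with the library of 1 region) they were 6%, 7% and 4%. FOXA1 and FOXA2 (SD 0.37 and 0.59), with 2 strata, were called in 0% at any change, and adjustment lowers the power of all these tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.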

Results

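Peak lists from 80 CUT&RUN libraries described where ARID1B, a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex, and 2 histone marks lay in HepG2 and HLF cells. Cells had or lacked ARID1B and received sorafenib, a multikinase inhibitor used against hepatocellular carcinoma, or its vehicle. HepG2 is a liver tumour line that keeps many hepatocyte genes active, and HLF is known as a poorly differentiated hepatocellular carcinoma line. H3K27ac marks active promoters and enhancers, H3K4me3 marks promoters, and FOXA1 and FOXA2 are pioneer factors of liver chromatin. The series asks whether loss of ARID1B alters chromatin and the response to sorafenib. Across the 16 IgG libraries the lists held 15 to 782 peak regions, with a median of 340 in HepG2 and 311.5 in HLF (n = 8 each). The read depth behind the lists is not given in the sources used here.

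ARID1B peaks fell in number in the KO. In HepG2 under DMSO they numbered 25199.5 ± 4521 in WT and 3073 ± 642 in KO (SD, n = 2 each), and in HLF 16962 ± 8721 and 3424.5 ± 1672. Over both lines and treatments the KO held 0.0786 times the WT number (mean log2 ratio −3.67, two-sided exact permutation p = 0.0031, adjusted p = 0.0432 over 14 tests), and the ratio was below 1 in 4 of 4 strata. In HepG2, 3689 regions were present in 4 of 4 WT and 0 of 4 KO libraries, and 0 regions the other way. In HLF these numbers were 549 and 1, and 159 lost regions were shared by both lines against 47.8 for independent lists. That 47.8 takes all union regions as equally able to meet the criterion. Regions differ in strength, so the excess alone does not show a shared response. With the same number of strongest regions per library the counts of changed regions were 217 in HepG2 (137 only in WT and 80 only in KO) and 39 in HLF (31 and 8). The mean log2 ratio was −2.15 without HepG2 KO sorafenib replicate 1, which held 1 region, and −5.18 without replicate 2 of that group. The call was lost in 3 of 16 omissions of 1 library: without HepG2 WT sorafenib replicate 1 or 2 (exact permutation p = 0.0864 or 0.103, adjusted p = 0.605 or 0.724) and without HLF WT sorafenib replicate 1 (exact permutation p = 0.0077, adjusted p = 0.0540). With replicate numbers as a block the call was lost too (exact permutation p = 0.0078, adjusted p = 0.109). The library HLF KO sorafenib replicate 1 held 12401 ARID1B regions, within the WT range, against 1513 in replicate 2. Without it the HLF count of changed regions was 2051 in place of 550, and without all 4 doubtful libraries the mean log2 ratio was −2.53 (exact permutation p = 0.0031, adjusted p = 0.0432).

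The ARID1B gene itself (chromosome 6, 156776026 to 157210779, GRCh38) carried an H3K4me3 peak at its end in 4 of 4 KO and 4 of 4 WT libraries of each line. A promoter mark does not report on the protein, so it does not check the knockout. The ARID1B peaks that remained in the KO lay often at the other marks and at IgG peaks. Of 1342 regions found in both HepG2 KO DMSO libraries, 70.4% overlapped H3K27ac and 67.7% H3K4me3, against 0.935% ± 0.237 and 1.65% ± 0.430 (SD, 20 shifts) after shifting. Of the regions of each HepG2 KO DMSO library 19.2% and 15.8% lay at IgG peaks, against 3.05% and 3.53% in WT DMSO. In WT DMSO, 34.8% of 17560 HepG2 regions and 64.8% of 9742 HLF regions overlapped H3K27ac, and 24.8% and 24.5% lay at gene ends. In HepG2 WT sorafenib 75.6% of 8750 regions overlapped H3K27ac. The H3K27ac regions found in both libraries numbered 20090 there, 8806 in HepG2 WT DMSO and 11751 in HepG2 KO DMSO. With lists of such unlike length, whether a high share is particular to the KO is left open. In HepG2 WT DMSO the share was 11.9% with only peaks of −log10 q of at least 5.

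**Figure D1:**
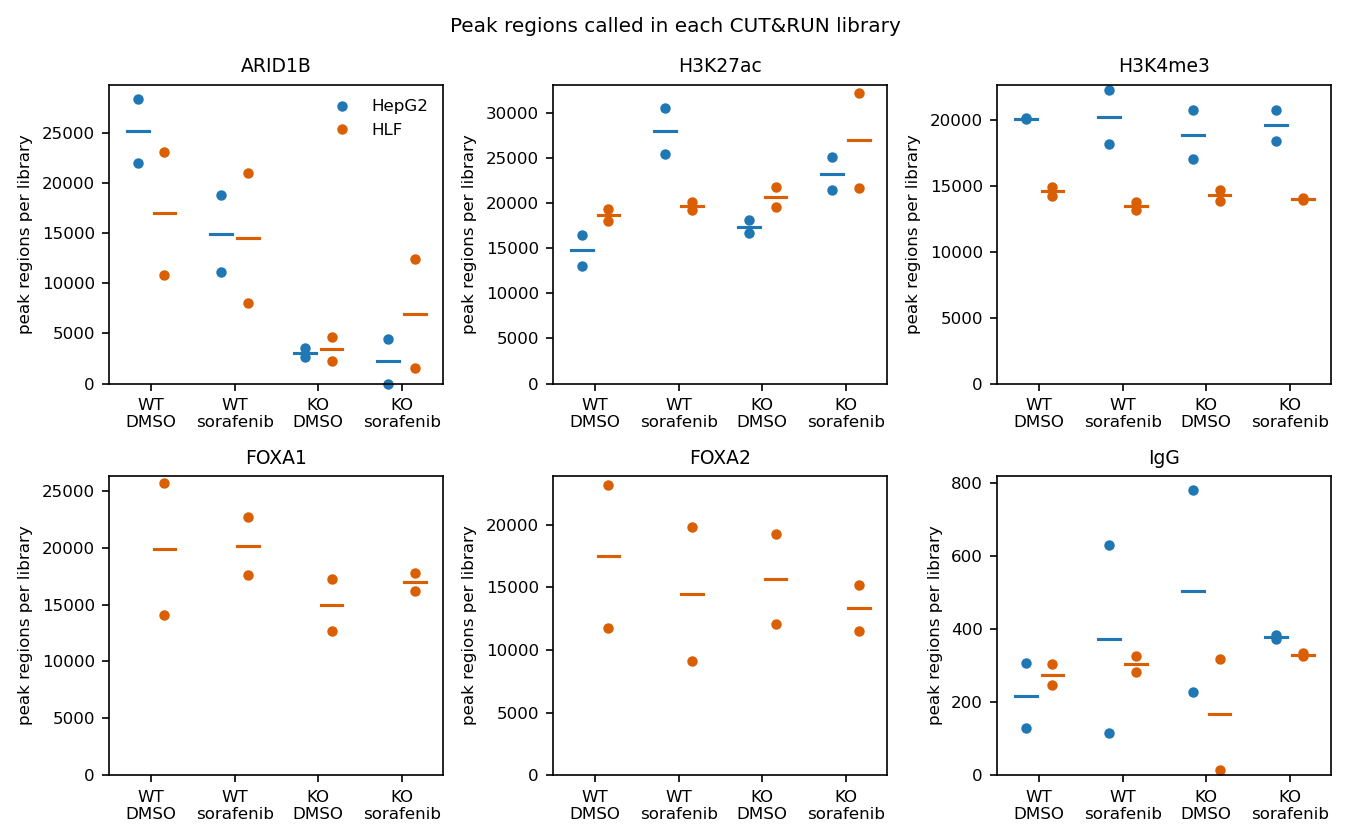
Number of peak regions per library (vertical axes, starting at 0) by genotype and treatment for each antibody; points are libraries of HepG2 (blue) or HLF (orange) and bars are means of 2. ARID1B in HepG2 under DMSO goes from 25199.5 in WT to 3073 in KO, and H3K27ac in HepG2 WT from 14760 with DMSO to 27996.5 with sorafenib.

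H3K4me3 separated the genotypes at 9 gene ends in both lines. In HepG2 22 gene ends were marked in 4 of 4 KO and 0 of 4 WT libraries and 27 the other way, and in HLF 27 and 24. Most thus met this criterion in 1 line only. That does not make them particular to that line, since some, such as SNAI2 and NR5A2 below, moved the same way in the other. The gene ends of NRCAM, a neuronal cell adhesion molecule, MYRIP, which links Rab27 vesicles to myosin, TWIST2, a transcription factor of epithelial-mesenchymal transition, and RAB3C, a small GTPase of regulated exocytosis, carried a peak in 8 of 8 KO and 0 of 8 WT libraries. CDH2, which encodes N-cadherin, KLF9, a glucocorticoid-induced transcription factor, DAB2, an endocytic adaptor, and SATL1 with its neighbour ZNF711 carried one in 0 of 8 KO and 8 of 8 WT libraries. CDH2 lies on chromosome 18 (27932879 to 28177130), TWIST2 on chromosome 2 (238848085 to 238910534), NRCAM on chromosome 7 (108147649 to 108456720), KLF9 on chromosome 9 (70384604 to 70414657) and DAB2 on chromosome 5 (39371677 to 39424980). SNAI2, another transcription factor of epithelial-mesenchymal transition, was marked in 4 of 4 KO and 0 of 4 WT libraries of HepG2 and in 1 and 0 of HLF (two-sided exact p = 0.0278, adjusted p = 1), and APCDD1, a WNT inhibitor, in 0 and 4 of HepG2 and in none of HLF (exact p = 0.0556, adjusted p = 1). NR5A2, a nuclear receptor of hepatocytes, was marked in 0 KO and 4 WT libraries of HLF and in 3 and 4 of HepG2 (exact p = 0.0278, adjusted p = 1).

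Each of those 9 genes had the smallest p the stratified exact test allows, 0.0015 two-sided, and an adjusted p of 0.356, so none passed. In the unstratified Fisher exact test the same 9 genes had p = 0.000155 and adjusted p = 0.0363, two-sided, and passed. Over all 2073 gene ends able to vary, 36 were marked in more KO and 24 in more WT libraries at an unadjusted exact p under 0.05, and 0 passed adjustment (0 adjusted over the list alone, 53 list genes). Among union regions, 72 were gained and 141 lost in HepG2 KO, and 53 gained and 35 lost in HLF KO, more than in any of the other 34 splits of the 8 libraries of either line. With the same number of strongest regions per library HepG2 had 106 only in KO and 92 only in WT, so the excess of lost ones there did not hold, and HLF had 51 and 37. Omitting HepG2 WT sorafenib replicate 2 gave 372 in place of 213, and omitting HLF WT or KO sorafenib replicate 2 gave 147 in place of 88. Of the changed regions, 9 gained and 4 lost regions were shared by both lines, against 0.132 and 0.175 for independent lists. These values again take all regions as equally able to meet the criterion. The number of H3K4me3 peak regions gave no passing difference (KO over WT 0.982, exact permutation p = 0.654, adjusted p = 0.878).

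**Figure D2:**
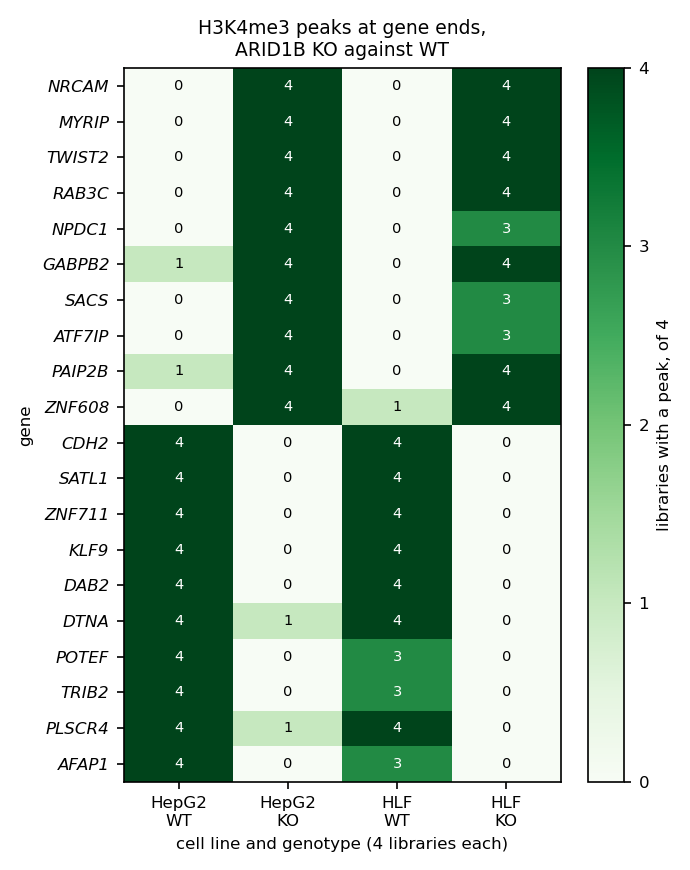
Number of libraries, of 4, with an H3K4me3 peak at the end of each gene (vertical axis) by cell line and genotype (horizontal axis), for the 10 genes per direction with the smallest exact p. NRCAM, MYRIP, TWIST2 and RAB3C are at 4 of 4 in KO and 0 of 4 in WT of both lines, and CDH2, SATL1, ZNF711, KLF9 and DAB2 the other way.

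As called, H3K27ac regions differed between genotypes in HLF. In HLF 207 H3K27ac regions were gained and 58 lost in the KO, more than in any of the other 34 splits. With the same number of strongest regions per library 90 were present only in KO and 100 only in WT, so the excess of gained ones did not hold. HepG2 then had 87 and 100, so the larger count in HLF did not hold either. With 13090 regions in every library of both lines HLF had 58 only in KO and 91 only in WT. Splits were not run at equal numbers. Distal were 150 of the gained and 56 of the lost ones, a share not tested against that of all regions. Gene ends marked in 4 of 4 KO and 0 of 4 WT libraries numbered 66 in HLF and 17 in HepG2, and 1 in each the other way. The strongest gained ones lay 16842 bp from GK, the glycerol kinase gene (chromosome X, 30748305 to 30749523), inside ANO3 (chromosome 11, 26596484 to 26597956) and inside RUNX3, a runt-domain transcription factor gene (chromosome 1, 24910632 to 24911543). A lost one lay inside PCDH15 (chromosome 10, 53956909 to 53958006). In HepG2 52 regions were present only in KO and 79 only in WT libraries, the latter with the strongest distal ones inside PDK2 (chromosome 17, 50101622 to 50102483) and 20751 bp from SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 13, 80361878 to 80362729). That HepG2 count was reached in 7 of 35 splits, the largest being the split by treatment, but it lay above all 17 other splits with equal treatments on both sides, of which the highest gave 79. Without the doubtful H3K27ac library of each line the counts were 433 in place of 265 in HLF and 225 in place of 131 in HepG2, since a criterion on fewer libraries is easier to meet. The highest count with 1 library omitted was 480 in HLF, without KO DMSO replicate 1, and 379 in HepG2, without WT DMSO replicate 2.

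At gene ends, EMX1, a homeobox gene of forebrain development, carried H3K27ac in 8 of 8 KO and 0 of 8 WT libraries (two-sided exact p = 0.0015, adjusted p = 1). At least 1 such gene end appeared in 7 of 100 splits, with 5 as the highest other. CDO1, which starts cysteine breakdown, and the histone genes H2AC12 and H2BC12 were marked in 7 KO and 0 WT libraries as 3 and 4 of 4 per line, OSTM1 as 4 and 3, and PIAS4, a SUMO ligase, in 4 and 4 KO against 0 and 1 WT libraries (exact p = 0.0046, adjusted p = 1). DPYSL2, a protein of axon guidance, was marked in 1 KO against 7 WT libraries (exact p = 0.0139, adjusted p = 1). FOXA2 itself (chromosome 20, 22580998 to 22585490) was marked in 0 KO and 3 WT libraries of HepG2 and in 2 and 4 of HLF (exact p = 0.0417, adjusted p = 1). JUN, an AP-1 subunit, was marked in 4 KO and 0 WT libraries of HLF and in 3 and 3 of HepG2 (exact p = 0.120, adjusted p = 1). Of 7723 gene ends able to vary, 112 were marked in more KO and 8 in more WT libraries at an unadjusted exact p under 0.05, and 0 passed adjustment (0 adjusted over the list alone, 218 list genes). Without the doubtful libraries 91 in place of 120 had such a p. The number of H3K27ac regions was 1.10 times that of WT (exact permutation p = 0.261, adjusted p = 0.778).

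No list passed adjustment for KO against WT in either mark. For H3K27ac the smallest p belonged to the 18 liver transcription factors, marked in 47.9% of gene-library pairs in KO and 52.8% in WT (log odds difference −0.396, −0.654 in HepG2 and −0.138 in HLF, exact permutation p = 0.0046, adjusted p = 0.0926). Of its members 5 were marked in fewer and 5 in more KO than WT libraries, among the former FOXA2 and NR5A2. Counting only peaks of −log10 q of at least 5 turned the sign to 0.0329 (exact permutation p = 0.782), whereas the list passed with reference genes outside the lists and with either gene end (exact permutation p = 0.0015, adjusted p = 0.0309 in both). Receptor tyrosine kinases and RAF genes, which include targets of sorafenib, gave −0.175 (exact permutation p = 0.0216, adjusted p = 0.216), although their own share was 33.9% in KO and 33.3% in WT, with 2 members in more and 1 in fewer KO libraries, so the sign comes from the other genes. Ferroptosis and antioxidant genes stood at 73.7% in KO and 59.2% in WT (0.445, exact permutation p = 0.0864, adjusted p = 0.455), with −0.181 in HepG2 and 1.07 in HLF, so the value comes from HLF. Of its members 11 were marked in more KO libraries and 1 in fewer. Of fetal liver and progenitor genes 7 were marked in more and 3 in fewer KO libraries (0.204, exact permutation p = 0.313, adjusted p = 0.696), with DLK1, an oncofetal liver gene, in 6 of 8 KO and 0 of 8 WT libraries (exact p = 0.0139, adjusted p = 1). Hepatocyte function genes gave −0.182 for H3K27ac (60.6% in KO and 60.0% in WT, exact permutation p = 0.145, adjusted p = 0.484) and −0.217 for H3K4me3 (exact permutation p = 0.0478, adjusted p = 0.259). For H3K4me3 they passed at equal peak numbers (−0.222, exact permutation p = 0.0031, adjusted p = 0.0309) and with reference genes outside the lists (−0.283, exact permutation p = 0.0062, adjusted p = 0.0494). The mesenchymal list, which holds CDH2 and SNAI2, gave −0.0368 for H3K4me3 (exact permutation p = 0.719, adjusted p = 0.822), with 3 members marked in more and 2 in fewer KO libraries. Markers of blood cells were marked in 11.6% in KO and 11.6% in WT, and those of endothelial and stellate cells in 19.6% and 17.0% (exact permutation p = 0.589 for the latter, adjusted p = 0.715).

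H3K27ac peaks rose in number with sorafenib. HepG2 WT cells held 14760 ± 2362 regions with DMSO and 27996.5 ± 3655 with sorafenib, HepG2 KO cells 17395.5 ± 1034.5 and 23293.5 ± 2553, HLF WT cells 18700.0 ± 907 and 19723 ± 660.4, and HLF KO cells 20666.5 ± 1587 and 26965.5 ± 7424 (SD, n = 2 each). The mean ratio was 1.36 (log2 0.45, two-sided exact permutation p = 0.0062, adjusted p = 0.0432), above 1 in 4 of 4 strata. The rise in HLF KO rests on sorafenib replicate 2, with 32215 regions of median width 381 bp covering 15.1 Mb. Sorafenib replicate 1 held 21716 regions of 706 bp covering 17.2 Mb. The DMSO replicates held 19544 and 21789 regions of 734 and 697 bp, covering 15.8 and 17.0 Mb. In covered base pairs HLF KO thus showed no clear rise, since sorafenib replicate 2 lay below both DMSO libraries. The call is not robust: without the doubtful libraries the log2 was 0.36 and the call was lost (exact permutation p = 0.0216, adjusted p = 0.151), as it was for base pairs covered (0.45, exact permutation p = 0.0139, adjusted p = 0.0972). It was also lost in 6 of 16 omissions of 1 H3K27ac library, at an adjusted exact permutation p of 0.0540 without HepG2 KO DMSO replicate 2, 0.0648 without HLF WT DMSO or sorafenib replicate 1, 0.130 and 0.0864 without HLF KO DMSO replicate 1 and 2, and 0.0756 without HLF KO sorafenib replicate 2. The 3 omissions that ended the ARID1B call ended this one too, since both share 1 adjustment. With replicate numbers as a block the H3K27ac call was lost as well (exact permutation p = 0.0156, adjusted p = 0.109). In HepG2 631 regions were present in 4 of 4 sorafenib and 0 of 4 DMSO libraries and 3 the other way, more than in any of the other 34 splits. Of the gained ones 504 were distal. The strongest lay 1373731 bp from WSB1, its nearest gene (chromosome 17, 25920048 to 25920382). It was followed by one 196813 bp from LOC124903767 (chromosome 16, 34586635 to 34587024). No list of excluded regions was applied here, so mapping artefacts at these sites, both far from any protein-coding gene, were not ruled out. Next came one inside PTPRK, a receptor phosphatase gene (chromosome 6, 128505347 to 128506071). With the same number of strongest regions taken from every library, 72 were present only with sorafenib and 36 only with DMSO, and without HepG2 KO sorafenib replicate 2, which eases the criterion, 1215 regions met it. In HLF 41 were present only with sorafenib and 10 only with DMSO, a count reached in 18 of 35 splits, and with equal numbers the direction turned, to 18 and 27. The response of the 2 lines was not told apart (log2 difference of HepG2 minus HLF 0.45, exact permutation p = 0.196).

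All HepG2 sorafenib lists of H3K27ac were longer (21488 to 30581 regions) than the DMSO lists (13090 to 18127). Gene ends near the calling threshold may thus be called only with the drug. For the genes named here this was not told apart from a change in signal. Among genes, PGK1, of glycolysis, and SMARCC2, a core SWI/SNF subunit, carried H3K27ac in 4 of 4 sorafenib and 0 of 4 DMSO libraries of HepG2. In HLF these genes were marked in 4 and 4, and 2 and 2 libraries (exact p = 0.0556 and 0.153, adjusted p = 1 each). F11, the liver-made coagulation factor XI gene, and UBB, a ubiquitin gene, behaved like PGK1 in their counts (exact p = 0.0556). ICAM4 was marked in 8 of 8 sorafenib and 1 of 8 DMSO libraries (exact p = 0.0046), MGMT, a DNA repair gene, in 6 and 0, and SULT1C4, a sulfotransferase gene, in 7 and 1 (exact p = 0.0139 each, adjusted p = 1 for all 3). GPC3, an oncofetal surface marker of hepatocellular carcinoma, was marked in 3 and 1 libraries of HepG2 and in 3 and 0 of HLF (exact p = 0.0417, adjusted p = 1). SPRY4, a feedback inhibitor of MAPK signalling, was marked in 2 sorafenib and 4 DMSO libraries of HepG2 and in 1 and 3 of HLF (exact p = 0.125, adjusted p = 1). Over 7733 gene ends able to vary, 84 were marked in more and 0 in fewer sorafenib libraries at an unadjusted exact p under 0.05, and 0 passed adjustment (0 adjusted over the list alone, 219 list genes). Without the doubtful libraries 93 had such a p.

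No list passed for sorafenib. Receptor tyrosine kinases and RAF genes gave the smallest p for H3K27ac (log odds difference −0.182, exact permutation p = 0.0201, adjusted p = 0.401), but their own share was 33.9% with sorafenib and 33.3% with DMSO. Of 21 members 3 were marked in more sorafenib libraries, 1 in fewer and 17 equally, so the sign reflects a larger share of all genes marked with sorafenib. Of the integrated stress and unfolded protein response genes 12 of 18 were marked in more sorafenib libraries and 0 in fewer (0.248, exact permutation p = 0.113, adjusted p = 0.445). The SWI/SNF subunits stood at 72.0% with sorafenib and 60.0% with DMSO (0.341, exact permutation p = 0.0849, adjusted p = 0.445), and 13 of 25 were marked in more sorafenib libraries. MAPK feedback genes gave −0.246 (exact permutation p = 0.214, adjusted p = 0.477), proliferation genes −0.492 (exact permutation p = 0.110, adjusted p = 0.445), and housekeeping genes, the control list, 0.266 (exact permutation p = 0.156, adjusted p = 0.445). The housekeeping value was 0.677 in HepG2 and −0.144 in HLF.

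H3K4me3 gave no passing difference with sorafenib. Its number of regions was 0.985 times that with DMSO (exact permutation p = 0.690, adjusted p = 0.878). PCGF2, a Polycomb group gene, was marked in 0 sorafenib and 4 DMSO libraries of HepG2 and in 1 and 3 of HLF (exact p = 0.0262, adjusted p = 1), and 2 of 2025 gene ends had an unadjusted exact p under 0.05, with 0 after adjustment (0 adjusted over the list alone, 51 list genes). Regions present only with sorafenib or only with DMSO numbered 37 and 13 in HepG2 and 3 and 28 in HLF, counts reached in 7 and 5 of 35 splits. ARID1B regions in WT numbered 0.688 times those with DMSO (exact permutation p = 0.222, adjusted p = 0.778).

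The response to sorafenib was not shown to depend on genotype. The ratio of the KO response to the WT response in H3K27ac regions was 0.924 (log2 −0.11, exact permutation p = 0.660, adjusted p = 0.878), and for H3K4me3, FOXA1 and FOXA2 it was 1.05, 1.09 and 1.06 (exact permutation p = 0.497, 0.778 and 0.944, adjusted p = 0.878, 0.897 and 0.944). As called, the H3K27ac value averages lines that run opposite ways, with a log2 response of 0.93 in WT and 0.42 in KO of HepG2 and of 0.08 and 0.36 in HLF. The 0.36 rests on HLF KO sorafenib replicate 2, the library with narrow regions. Without that library the ratio of the responses over both lines was log2 −0.26. Within HepG2 WT 5154 H3K27ac regions were present in 2 of 2 sorafenib and 0 of 2 DMSO libraries and 86 the other way, and within HepG2 KO 2539 and 380. Of the former 631 were shared, against 306.5 for independent lists, a value that takes all regions as equally able to meet the criterion. In HLF these counts were 803 and 514 in WT and 1097 and 289 in KO. In HepG2 the totals of 5240 in WT and 2919 in KO lay above other splits of the same libraries (813 to 987 and 1089 to 1219). In HLF the totals of 1317 and 1386 did not exceed the highest other split (1426 to 1490 in WT and 1038 to 2151 in KO).

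**Figure D3:**
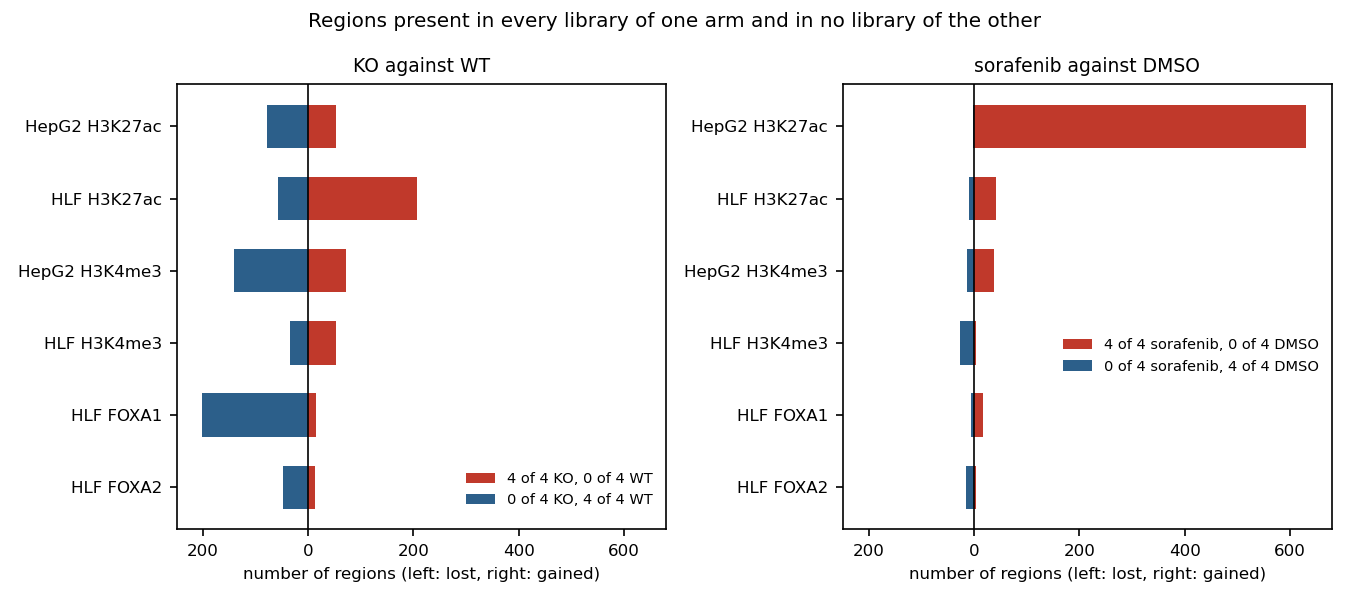
Number of union regions (horizontal axes) present in 4 of 4 libraries of 1 arm and 0 of 4 of the other, to the right those only in KO or sorafenib and to the left those only in WT or DMSO, for each line and antibody; ARID1B is left out for scale. HepG2 H3K27ac with sorafenib stands at 631 and 3, HLF H3K27ac in KO at 207 and 58, and HLF FOXA1 in KO at 15 and 202.

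FOXA1 lost regions in HLF KO. In HLF 202 FOXA1 regions were lost and 15 gained in the KO, more than in any of the other 34 splits although the highest other gave 191, and 177 of the lost ones were distal. At equal numbers 102 were present only in WT and 46 only in KO. The strongest lost one lay inside GPC3 (chromosome X, 133884521 to 133885646), and others inside LRRC4C (chromosome 11, 41189869 to 41190976) and inside SEMA3A, an axon guidance gene (chromosome 7, 84022270 to 84023124). The strongest gained one lay inside PPM1L (chromosome 3, 160757265 to 160757963). FOXA2 had 48 regions only in WT and 13 only in KO, a count reached in 11 of 35 splits, which take no account of the order of the libraries by replicate number. Among these FOXA2 regions were the GPC3 site (133884570 to 133885353) and the PPM1L site (160757255 to 160757942). Swapping genotypes only within same-numbered pairs, a pairing the labels do not state, the FOXA2 count of 61 stood against 26 as the highest other of 8 swaps. The number of FOXA1 regions in KO was 0.813 times that in WT (exact permutation p = 0.278, adjusted p = 0.778) and that of FOXA2 0.952 (exact permutation p = 0.833, adjusted p = 0.897). With sorafenib the ratios were 1.10 and 0.841 (exact permutation p = 0.611 and 0.5, adjusted p = 0.878 for both). With sorafenib 16 FOXA1 regions were present only with the drug and 7 only with DMSO, and 3 and 16 for FOXA2, counts reached in 30 and 26 of 35 splits. Without HLF WT DMSO FOXA1 replicate 1 the KO count of changed FOXA1 regions was 611, and without HLF WT sorafenib replicate 2 it was 534. Without HLF KO DMSO replicate 2 it was 352, and without HLF KO sorafenib replicate 1 it was 356.

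Peaks of the ARID1B antibody and of the FOXA factors lay at many of the same places in HLF. In WT DMSO cells 47.6% of 13001 FOXA1 regions and 50.8% of 10787 FOXA2 regions overlapped ARID1B, against 0.748% ± 0.0759 and 0.813% ± 0.170 (SD, 20 shifts) after shifting, and 84.2% of FOXA2 regions overlapped FOXA1. With 1 library in place of both, the share of FOXA1 regions at ARID1B ranged from 32.9% without HLF WT DMSO FOXA1 replicate 1 to 71.7% without HLF WT DMSO ARID1B replicate 1. Of the 9742 ARID1B regions in WT DMSO 63.5% lay at FOXA1 and 56.3% at FOXA2. Of the 1716 left in KO DMSO 83.8% and 85.0% did, so such overlap does not by itself show ARID1B binding. In KO DMSO 13.6% of FOXA1 and 13.9% of FOXA2 regions lay at that shorter ARID1B list. H3K27ac regions gained in HLF KO under DMSO carried FOXA1 in KO at 16.5% of 1317 against 42.3% of 11910 kept ones, and FOXA2 at 16.9% against 43.6%. The odds ratios within strength bins were 0.354 (0.300 to 0.417) and 0.378 (0.321 to 0.445) (permutation p = 1e-05 each, the smallest possible, adjusted p = 2e-05). Gained regions are chosen for absence in WT, which favours regions near the calling threshold, and how far the strength bins account for this was not tested. For regions lost in KO the odds ratios did not pass. They were 0.857 (permutation p = 0.0697, adjusted p = 0.0930) for ARID1B in HepG2, 1.16 (permutation p = 0.119, adjusted p = 0.136) in HLF, 1.07 (permutation p = 0.479, adjusted p = 0.479) for FOXA1 and 1.21 (permutation p = 0.0506, adjusted p = 0.0810) for FOXA2. Regions are not replicates. Without strength bins the last 3 odds ratios were 0.567, 0.604 and 0.677, and without HLF WT DMSO H3K27ac replicate 1 they were 0.564, 0.604 and 0.665, so the direction at lost regions is open.

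Libraries labelled HLF and HepG2 held closely similar H3K27ac regions. Of 6187 distal H3K27ac regions found in all 4 WT HLF libraries 99.0% were found in at least 1 WT HepG2 library, against 3.95% ± 0.790 (SD, 20 shifts) after shifting. The mean Jaccard index of H3K27ac between the lines was 0.415 (16 pairs), beside 0.433 for replicates in HepG2 and 0.482 in HLF (4 pairs each), and for H3K4me3 it was 0.665 beside 0.779 for replicates in either line. HNF4A, the hepatocyte nuclear receptor gene, named here after its values were seen, carried H3K27ac in 8 of 8 HLF and 7 of 8 HepG2 libraries. Whether results found in both labels come from independent cell backgrounds is left open.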

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

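The alternatives using either gene end, the removal of 4 doubtful libraries and the comparison of the lines were chosen only after seeing the data. Peak lists without read counts leave depth open, so a region missing from a list can be one that a shallow library did not reach. Of the results that answer a comparison, 762 alternative values kept their direction and side of the adjusted threshold, 191 counts or shares moved, 11 passed only in the alternative, 17 passed only in the main test and 17 reversed. Of values for single genes, lists and regions, 3964 stayed, 292 moved, 17 passed only in the alternative and 1 reversed. A change of sign counts as reversed where either unadjusted p was under 0.05. That 1 was the H3K27ac log odds of the liver transcription factors in KO, 0.0329 (exact permutation p = 0.782) with only peaks of −log10 q of at least 5. Where no reason is given below, the cause was not tested.

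With only peaks of −log10 q of at least 5, changed regions in KO numbered 1789 and 359 for ARID1B in HepG2 and HLF, 31 for H3K27ac in HepG2 and 128 for H3K4me3 in HepG2. With sorafenib they numbered 25 for H3K27ac, 12 for H3K4me3, 14 for FOXA1 and 8 for FOXA2, all in HLF. Gene ends with an unadjusted exact p under 0.05 with sorafenib numbered 231 for H3K27ac and 5 for H3K4me3. The odds ratios at lost H3K27ac regions were 1.44 for FOXA1 (permutation p = 0.0169) and 1.54 for FOXA2 (permutation p = 0.0058). Of HLF WT DMSO regions, 38.0% of FOXA1 and 40.9% of FOXA2 lay at ARID1B, and 46.5% of ARID1B at H3K27ac, against 11.9% in HepG2. A stricter threshold removes regions by construction.

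With the same number of strongest regions per library, ARID1B changed regions in KO numbered 217 in HepG2 and 39 in HLF and those of FOXA2 122. For ARID1B a KO list set the number, which removes most WT regions. With sorafenib H3K27ac in HepG2 gave 108, H3K4me3 in HLF 9, and 4 H3K4me3 gene ends had an unadjusted exact p under 0.05. In this setting 1 list passed, hepatocyte function for H3K4me3 in KO (log odds difference −0.222, exact permutation p = 0.0031, adjusted p = 0.0309). With reference genes outside the lists, 2 lists passed for H3K27ac in KO, liver transcription factors (−0.573, exact permutation p = 0.0015, adjusted p = 0.0309) and the WNT pathway (−0.498, exact permutation p = 0.0046, adjusted p = 0.0463), and 1 for H3K4me3, hepatocyte function (−0.283, exact permutation p = 0.0062, adjusted p = 0.0494). With either gene end, liver transcription factors passed for H3K27ac as the 1 list in KO (−0.483, exact permutation p = 0.0015, adjusted p = 0.0309) and the 1 list with sorafenib (0.230, exact permutation p = 0.0015, adjusted p = 0.0309). With a 2 kb window 1 list passed for H3K4me3 in KO, and 1 H3K4me3 gene end had an unadjusted exact p under 0.05 with sorafenib. The unstratified Fisher exact test gave 9 adjusted H3K4me3 gene ends in KO.

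In 1 kb bins, which count wide regions more than once, changed bins in KO numbered 853 for ARID1B in HLF, 255 and 488 for H3K27ac in HepG2 and HLF, 434 and 228 for H3K4me3, 348 for FOXA1 and 97 for FOXA2. With sorafenib they numbered 1148 and 93 for H3K27ac, 188 and 65 for H3K4me3, 40 for FOXA1 and 31 for FOXA2. The odds ratio of ARID1B at lost H3K27ac regions in HepG2 was 0.708 in bins (permutation p = 1e-05). Without strength bins the odds ratios at lost regions were 0.587 for ARID1B in HepG2, 0.567 in HLF, 0.604 for FOXA1 and 0.677 for FOXA2. With sorafenib in place of DMSO libraries they were 0.401 (permutation p = 1e-05) for ARID1B in HepG2 and 0.741 (permutation p = 0.0384, adjusted p = 0.0512) in HLF. The sorafenib call of H3K27ac region numbers was lost for base pairs covered (log2 0.45, exact permutation p = 0.0139, adjusted p = 0.0972) and without the 4 doubtful libraries (0.36, exact permutation p = 0.0216, adjusted p = 0.151). Without the 4 doubtful libraries, changed regions in KO numbered 2051 for ARID1B in HLF and 225 and 433 for H3K27ac in HepG2 and HLF, and with sorafenib 958 and 96. Fewer libraries make the criterion easier to meet.

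Replicate numbers were not taken as pairs, since the labels do not state it. Replicate 1 had more H3K27ac regions in 4 of 4 HepG2 groups, an order that goes with the number, but in 1 of 4 HLF groups. In HepG2 it had more in 1 of 4 groups for ARID1B and 2 of 4 for H3K4me3. For ARID1B, FOXA1 and FOXA2 in HLF the order also went with the number: replicate 2 had more regions in 6 of 6 groups under DMSO and replicate 1 in 6 of 6 under sorafenib, which is a hint from the data of a pairing of WT with KO there. FOXA1 regions were fewer in KO in 4 of 4 same-numbered pairs (exact p = 0.125 with the block, the smallest possible). Swapping genotypes only within such pairs, the FOXA1 count of 217 stood against 53 as the highest other of 8 swaps, the FOXA2 count of 61 against 26 and the HLF ARID1B count of 550 against 34. Each was thus 1 of 8, the lowest share possible, which cannot pass a threshold of 0.05. With replicate numbers as a block both called region numbers were lost, ARID1B in KO (log2 −3.67, exact permutation p = 0.0078, the smallest possible) and H3K27ac with sorafenib (0.45, exact permutation p = 0.0156), each at adjusted p = 0.109. In this setting gene ends with an unadjusted exact p under 0.05 numbered 34 for H3K27ac and 33 for H3K4me3 in KO, and 20 and 1 with sorafenib, where the block allows fewer relabellings.

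Leaving out 1 library, or all of 1 replicate number, gave log2 ratios of ARID1B region numbers from −5.18 to −2.15 and H3K27ac ratios with sorafenib from 0.37 to 0.52. The ARID1B call was lost without HepG2 WT sorafenib replicate 1 (−3.76, exact permutation p = 0.0864) or replicate 2 (−3.57, exact permutation p = 0.103) and without HLF WT sorafenib replicate 1 (−3.49, exact permutation p = 0.0077, adjusted p = 0.0540). The H3K27ac call was lost without HepG2 KO DMSO replicate 2 (0.43, adjusted exact permutation p = 0.0540), HLF WT DMSO replicate 1 (0.43, 0.0648), HLF WT sorafenib replicate 1 (0.44, 0.0648), HLF KO DMSO replicate 1 (0.43, 0.130) or 2 (0.46, 0.0864) or HLF KO sorafenib replicate 2 (0.37, 0.0756). The 3 omissions that ended the ARID1B call ended it too, and both calls were lost without all libraries of either replicate number, where 1 against 1 per stratum allows no exact p under 0.125. Without HLF KO sorafenib H3K27ac replicate 1, liver transcription factors passed in KO, so the lists numbered 0 to 1, and without HLF WT sorafenib H3K4me3 replicate 1 hepatocyte function did, again 0 to 1. Gene ends with an unadjusted exact p under 0.05 in KO ranged from 0 to 197 for H3K27ac (197 without HepG2 WT sorafenib replicate 1, 182 without HepG2 KO sorafenib replicate 2 or HLF WT sorafenib replicate 1) and from 0 to 71 for H3K4me3. With sorafenib they ranged from 0 to 137 for H3K27ac (131 without HepG2 KO DMSO replicate 1, 137 without HepG2 KO sorafenib replicate 2, 132 without HLF WT DMSO replicate 2) and from 0 to 9 for H3K4me3. The lowest counts of 0 come from leaving out a whole replicate number.

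Changed regions over the same omissions, each of which eases the criterion, ranged in KO from 3691 to 9011 for ARID1B in HepG2 (7753 without WT sorafenib replicate 1). For ARID1B in HLF they ranged from 557 to 3740 (1112 without WT DMSO replicate 1, 1882 without WT sorafenib replicate 2, 2051 without KO sorafenib replicate 1). For H3K27ac in KO they ranged from 199 to 1507 in HepG2 (379 without WT DMSO replicate 2) and from 363 to 2266 in HLF (480 without KO DMSO replicate 1, 465 without WT sorafenib replicate 2). For H3K4me3 in KO they ranged from 273 to 1232 in HepG2 (372 without WT sorafenib replicate 2) and from 116 to 750 in HLF (134 without WT DMSO replicate 2, 147 without WT or KO sorafenib replicate 2). FOXA1 in KO ranged from 268 to 1953 (611 without WT DMSO replicate 1) and FOXA2 from 88 to 1417 (366 without WT sorafenib replicate 2). With sorafenib the ranges were 778 to 3673 and 80 to 1871 for H3K27ac in HepG2 and HLF (1215 without HepG2 KO sorafenib replicate 2, 192 without HLF KO sorafenib replicate 1), 76 to 781 and 42 to 477 for H3K4me3, 49 to 2421 for FOXA1 and 35 to 4739 for FOXA2.

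The odds ratios at lost H3K27ac regions ranged from 0.375 to 0.883 for ARID1B in HepG2, from 0.537 to 1.16 in HLF, from 0.478 to 1.08 for FOXA1 and from 0.551 to 1.21 for FOXA2. In HLF they lay below 1 without WT DMSO H3K27ac replicate 1 (0.564, 0.604 and 0.665) or replicate 2 (0.548, 0.598 and 0.688), and for FOXA1 also without its WT DMSO replicate 1 (0.797). Without replicate 1 of all groups they were 0.537, 0.478 and 0.551, and without replicate 2 they were 0.617, 0.696 and 0.749. With 1 WT H3K27ac library, regions no longer need both, so weaker ones enter. The odds ratios of FOXA1 and FOXA2 at gained regions passed in every omission. Shares at ARID1B in HLF WT DMSO ranged from 32.9% to 71.7% for FOXA1 and from 35.2% to 74.2% for FOXA2, and shares of ARID1B regions at H3K27ac from 44.0% to 73.9% in HLF and from 25.5% to 49.0% in HepG2.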

Other observations

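Tests chosen only after the results had been seen were those of 1 line under both labels, of a swap of libraries, of the splits of changed regions and of the 9 separated gene ends. Other gene groups had no passing difference. WNT pathway genes carried H3K27ac in 59.8% of gene-library pairs in KO and 62.5% in WT (log odds difference −0.322, two-sided exact permutation p = 0.0910, adjusted p = 0.455), where CTNNB1, the beta-catenin gene, was marked in 8 KO and 4 WT libraries and LGR5, a receptor of R-spondins, in 4 and 8 (exact p = 0.0833, adjusted p = 1 each). Drug transport and metabolism genes stood at 22.9% and 13.9% (0.430, exact permutation p = 0.128, adjusted p = 0.484), and AP-1 and YAP/TEAD genes at 55.9% and 44.9% (0.220, exact permutation p = 0.292, adjusted p = 0.696). BRD7, a PBAF subunit, was marked in 7 KO and 2 WT libraries (exact p = 0.0417, adjusted p = 1). With sorafenib, NUPR1, a stress-induced gene, was marked in 8 sorafenib and 4 DMSO libraries and GADD45A, a p53 target, in 8 and 4 (exact p = 0.0833, adjusted p = 1 each).

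The H3K27ac lists of HLF and HepG2 are close enough to ask whether both labels could cover cells of 1 line. As called, 133 H3K27ac regions separated the labels in WT (4 of 4 against 0 of 4), fewer than the 265 between genotypes of HLF, but H3K4me3 separated 60 and 1169 in WT. With 13090 H3K27ac regions in every library of both lines 196 in WT and 197 in KO separated the labels, close to the 187 between genotypes of HepG2 (149 in HLF, or 190 with the number set within HLF), and with 13170 H3K4me3 regions 208 and 154, against 129 and 88 (198 with the number set within HepG2), so 1 line is neither shown nor excluded, a verdict reached after these counts were seen. Lists that hold only strong regions shared by most cells were not told apart from this, since 99.0% of distal and 99.8% of gene-end WT HLF regions were found in HepG2, a measure whose ceiling was recognised only after its values were seen. No biological explanation was tested, and genotyping of the cells could settle it.

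HLF KO sorafenib ARID1B replicate 1 had 12401 regions, more than the 7989 of the smallest HLF WT library. Nonspecific background cannot be told apart, since 65.2% lay at regions of both WT DMSO or both WT sorafenib libraries, but so did 86.9% to 90.4% of the regions of the other 3 KO libraries. That signal left in KO also lies at WT sites was recognised only after these shares were seen, so the bound of 50% written beforehand was wrong. Replicate 1 held 70.9% of those WT regions, against 11.5% to 35.5% in the other 3 KO libraries. The WT libraries, which define the regions, held 63.6% to 97.6%. Its closest library was HLF WT DMSO ARID1B replicate 1 (Jaccard index 0.403). A longer list finds more of these regions, so the values do not decide. A swap with a WT library would leave a WT library at KO level, but the smallest WT library held 7989 regions and the largest other KO library 4607. A single wrong label, remaining ARID1B protein in that culture or carry-over of material might each give this list, and they were not told apart.

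The 631 H3K27ac regions of HepG2 found only with sorafenib may in part come from longer lists. At equal peak numbers 72 regions were found only with sorafenib and 36 only with DMSO, a ratio of 2 (95% exact interval 1.32 to 3.07, which takes regions as independent and holds no spread between libraries), which cannot tell between longer lists and a change of order. The value fell on the bound written beforehand, so the use of its interval was chosen after it was seen. Of the 631, 0.792% lay at an IgG peak, against 1.98% of all regions, so background at IgG peaks is a poor account. The HepG2 IgG libraries held only 115 to 782 regions each, so this overlap cannot decide on background elsewhere, which was not tested. A biological response of HepG2 to sorafenib remains open.

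Splits of the 8 libraries of each line gave these numbers of changed regions for KO against WT. ARID1B in HepG2 had 3689, with 1 of 35 splits as large (the real one) and 351 as the highest other. ARID1B in HLF had 550, reached in 2 of 35 splits, and the highest other, at 1557, put KO sorafenib replicate 1 with WT libraries, so it points to a structure of the samples. H3K27ac had 131 in HepG2 (7 of 35, highest other 634, the split by treatment, again a structure of the samples, and 79 as the highest of the 17 other splits with equal treatments on both sides) and 265 in HLF (1 of 35, highest other 116). H3K4me3 had 213 in HepG2 (1 of 35, highest other 108) and 88 in HLF (1 of 35, highest other 41). FOXA1 had 217 (1 of 35, highest other 191) and FOXA2 61 (11 of 35, highest other 465, which points to a structure of the samples). Both highest other splits put KO and WT DMSO replicate 1 with KO and WT sorafenib replicate 2, which follows the order of region numbers within groups, so the FOXA libraries share a structure other than genotype.

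For sorafenib against DMSO, H3K27ac had 634 changed regions in HepG2 (1 of 35 splits, highest other 253) and 51 in HLF (18 of 35, highest other 265, the split by genotype). H3K4me3 had 50 in HepG2 (7 of 35, highest other 213) and 31 in HLF (5 of 35, highest other 88), in both lines the split by genotype. FOXA1 had 23 (30 of 35, highest other 217, by genotype) and FOXA2 19 (26 of 35, highest other 465). These higher counts point to a structure of the samples.

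In 100 splits within strata, gene ends with an unadjusted exact p under 0.05 were as many as the 120 for H3K27ac in KO in 2 splits, with 154 as the highest other, and as many as the 84 with sorafenib in 1, with 79 as the highest other. For H3K4me3 the 60 in KO were reached in 1 split, with 28 as the highest other, and the 2 with sorafenib in 59, with 9 as the highest other. The 9 H3K4me3 gene ends that separated all 8 KO from all 8 WT libraries were reached in 1 split, the real one, with 1 as the highest other. The 0 passing lists were reached in 100 of 100 splits in each of the 4 contrasts, which holds by definition for a count of 0 and decides nothing. The highest others were 2, 2, 1 and 2 for H3K27ac in KO and with sorafenib and H3K4me3 in KO and with sorafenib.

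The peak names inside the list of HepG2 KO DMSO H3K27ac replicate 2 carry another antibody's name, the only one of 80 lists with such a mismatch. Its Jaccard index was 0.410 with its own replicate and 0.410 with HLF KO DMSO H3K27ac replicate 1, its closest library.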
